A study of Arabidopsis thaliana with 18 samples.

How the data were processed

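Gene expression was measured on 18 Affymetrix ATH1 microarrays, 1-colour arrays on which each transcript is read by a probe set of short oligonucleotides. Arabidopsis thaliana seedlings of wild type (labelled Col-Luc) and the mutants rao1-1 and rao1-2 were sprayed with antimycin A or deionised water (mock). Each of the 6 groups held 3 arrays, and groups were taken from the sample labels. The labels number the replicates but do not say that they came from separate cultures, so p-values measure the spread between these samples, which may be technical.

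The deposited values are intensities on a linear scale, already normalized. RMA and GCRMA are named per the submitters' processing notes, without version, and which of them gave the deposited intensities is not given in the sources used here. They ranged from 1.61 to 64819.8. No genome build is named in the sources used here, and no coordinates are given. The log2 of each deposited intensity was taken with no pseudocount and no further normalization. Both methods make the arrays' distributions alike, so a change common to most transcripts would be removed, and changes are relative to the bulk of the probe sets. Array medians lay between 77.8 and 91.8. No pair of arrays held identical values.

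Of 22810 probe sets, the 64 control probe sets were left out of the tests, and 22746 were tested. The platform annotation supplied with the series gave 1 gene to 13513 probe sets and several genes to 503, and 8730 were unnamed here. Of the probe sets with 1 gene, 13436 were matched to the RefSeq gene table of assembly TAIR10.1, used for names only, and 77 were not matched and kept their given names. A probe set with several genes or no name entered the counts but was never named. In all, 13350 genes were named, 152 of them through several probe sets, of which the one with the highest mean over all arrays represents the gene. CDKE1 (AT5G63610), the gene in the title of the series, and AOX1A (AT3G22370), the alternative oxidase gene commonly used as a marker of mitochondrial retrograde signalling, were among the genes without a named probe set, and were not analysed here.

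A background limit was set at the least dense point between the lower and upper modes of all log2 values, at 4.25 (an intensity of 19.0). It was set after the values were seen and served only to describe levels. Over all arrays 62.0% of values lay above it. A probe set under the limit on all 3 arrays of a group has only a bound there, and its fold is given as "at least", computed on the means of log2 values with each value of the dim group under the limit set to the limit. No fold is given where both groups lay under the limit on all arrays or where the bound was under 1. The number of arrays limits the precision.

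Each probe set was fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 18 arrays (12 residual degrees of freedom) and moderated by eBayes. P-values were two-sided, adjusted by the Benjamini-Hochberg method over the 22746 probe sets, and a probe set was called at an adjusted p under 0.05. Adjusted p-values of genes are limma's throughout. The contrasts were antimycin A against mock in each genotype, each mutant against wild type within mock and within antimycin A, rao1-2 against rao1-1 within each treatment, and the differences between genotypes in the response to antimycin A. For the last, the mean of both mutants' responses was also set against the wild-type response. A difference in response is an interaction term, so that a transcript already raised under mock gives a negative difference at an equal level under antimycin A. Levels are means of intensities with their SD over 3 arrays, while changes are differences of mean log2 values with their SE.

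The groups, contrasts, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined, except where stated otherwise. Named genes were CDKE1 and AOX1A; the 10 probe sets higher and the 10 lower with the largest log2 change among those called and naming 1 gene, for the wild-type response, the difference in response of both mutants and each mutant under mock; and the 5 higher and 5 lower for the other comparisons. Replicate values of the groups compared were required not to overlap, except for differences in response. Of each gene list, up to 4 called members with the largest change were named, or the member with the smallest p where none was called. Other genes are named only as members of these lists or of gene families.

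The gene lists covered alternative respiration, mitochondrial dysfunction markers, detoxification, rapid stress and touch response, heat shock, photosynthesis, auxin response, expansins and wall loosening, respiratory complex III and cytochrome c, cold and abscisic acid, senescence markers and root markers, each with at least 3 members named here and so tested. Lists for jasmonate, mediator, cell cycle, mitochondrial chaperones, anthocyanin and flavonoid, glucosinolate and the circadian clock had fewer members named here and are given gene by gene. No member of the lists for retrograde transcription factors, reactive oxygen enzymes, salicylic acid and defence, energy starvation and floral organ markers was named here. Those 5 lists were not analysed. The lists were written from general knowledge, which includes published responses to antimycin A, so the direction of the dysfunction markers in wild type is not independent evidence. Lists were tested with camera at a preset correlation of 0.01 between genes, with camera at a correlation estimated from the data, and with fry, adjusted over the 12 lists of a comparison. Members are counted over all probe sets and adjusted over the list alone.

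Shared responders were probe sets called, and changed at least 2-fold, in the mean response over the 3 genotypes. Their median difference between mutant and wild type is given, and their mean difference was tested by an exact permutation of the 400 relabellings of arrays within treatment, two-sided. Overlaps between comparisons that share wild-type arrays were set beside 20 simulations of unchanged groups against shared controls. The steps were tested on simulated data with 200 changed probe sets among 22746. For the wild-type response, 71% of 2-fold and 95% of 4-fold changes were recovered, with 7 false calls among 173. For the difference in response of both mutants, 66% and 93% were recovered, with 3 false calls among 162. For the comparison of rao1-1 with wild type under mock, simulated without change, 0 calls were made by limma.

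The alternatives fixed beforehand were the replicate number as a block, quantile normalization again, leaving out the probe sets of lowest mean intensity, eBayes with trend and robust settings, array weights, leaving out each array in turn, a fold threshold, and a fit to the arrays compared alone. Centring each array on the probe sets above the background limit, centring on the added poly(A) control transcripts or on the 12 hybridisation controls above the limit (bacterial BioC and BioD and phage Cre, also compared between groups with limma, adjusted over the 12), and setting values under the limit to the limit were added after seeing the data. The alternatives for 2 overlaps between the mutants, of their levels under antimycin A and of their differences in response, were also added then, and the gene families of the closing section were formed after the results were seen. Figures were drawn with matplotlib 3.10.9.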

Results

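Transcripts were profiled in 14-day-old seedlings of wild type and of 2 mutants, rao1-1 and rao1-2, whose name stands for regulators of alternative oxidase 1a. The labels give antimycin A as an elicitor of mitochondrial retrograde signalling, and it is known to block electron transfer through respiratory complex III. Seedlings on Gamborg B5 medium with 3% sucrose grew at 22 °C in 16 h light and 8 h dark, after 48 h of stratification at 4 °C. They were sprayed with 50 µM antimycin A or with water, and whole green tissue was taken 3 h later. Each of the 6 groups, 3 genotypes by 2 treatments, held 3 arrays made from 400 ng of total RNA. On single arrays 61.8% to 62.3% of the probe sets lay above the background limit, and the mean correlation with the arrays of the same group, across probe sets, was 0.985 to 0.995. The lowest value belonged to replicate 1 of rao1-2 mock. The number of arrays limits the precision of the values that follow, which are intensities (mean ± SD, n = 3) or log2 changes (± SE).

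Control probe sets differed between groups as well. The 25S ribosomal RNA probe set had a mean log2 intensity of 12.81 ± 0.18 under mock and 13.65 ± 0.10 under antimycin A in wild type (SD, n = 3). In rao1-1 it went from 12.96 ± 0.07 to 14.20 ± 0.06, and in rao1-2 from 12.98 ± 0.06 to 14.03 ± 0.10 (SD, n = 3). In each genotype the 3 treated arrays lay above the 3 mock arrays, which chance gives in 10% of cases for either direction together. The 3' over 5' log2 ratio of actin was 1.88 under mock and 1.81 under antimycin A in wild type, 1.97 and 1.85 in rao1-1, and 1.94 and 1.74 in rao1-2. That of GAPDH was 0.36 and 0.15 in wild type, 0.35 and 0.36 in rao1-1, and 0.38 and 0.26 in rao1-2, and that of ubiquitin 0.39 and 0.46, 0.28 and 0.46, and 0.21 and 0.36. Of the 12 bacterial and phage control probe sets above the limit, added to check the hybridisation, 5 were lower in rao1-1 than in wild type under mock and 3 in rao1-2, and 0 passed between mutant and wild type under antimycin A or between treatments in wild type. The largest was BioC-3, at a mean log2 intensity of 8.31, 7.71 and 7.95 under mock in wild type, rao1-1 and rao1-2 and 8.32, 8.28 and 8.29 under antimycin A. For its difference in response, both mutants against wild type, the value was 0.46 ± 0.08 (adjusted p = 0.000504 over the 12), and the 4 Cre probe sets did not pass. The mutants' mock arrays thus differed from the others in added controls as well as in genotype, which bears on every comparison that uses them.

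The first comparison asked which transcripts antimycin A changed in wild type. Many transcripts with almost no signal under mock became abundant within 3 h. AT2G32020, a GNAT acetyltransferase gene on the list of mitochondrial dysfunction markers, went from 3.88 ± 0.255 to 5022 ± 1058, a rise of at least 261-fold (10.32 ± 0.14 on the log2 scale, adjusted p = 1.36e-14). AT2G04050, a MATE efflux transporter gene, rose at least 219.8-fold, and the glutathione transferase gene GSTU25 (AT1G17180) rose at least 166-fold. AT4G28460 rose at least 200.1-fold, AT1G74870 at least 148-fold, AT2G32140 at least 112-fold, AT4G28085 307-fold and AT1G22810 at least 97.7-fold. The lipase gene DLAH (AT1G30370) rose at least 47.3-fold and the calmodulin-like gene CML37 (AT5G42380) at least 58.7-fold. The largest falls were smaller. AT5G41900 went from 234 ± 29.7 to 13.0 ± 13.8, 26.7-fold lower (adjusted p = 0.000405). The wax ester synthase gene WSD1 (AT5G37300) fell at least 6.58-fold, the sugar transporter gene SWEET1 (AT1G21460) at least 7.72-fold, P1R1 (AT5G57780) 17.3-fold and AT5G43740 17.2-fold. AT3G26960 fell 16.5-fold, AT2G30890 at least 4.33-fold, AT3G56260 at least 5.76-fold, AT3G15720 at least 5.75-fold and AT1G20070 14.6-fold. These 20 genes had adjusted p-values of at most 0.000405, and their replicates did not overlap between treatments, which chance gives for 10% of unchanged probe sets.

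In all, 9822 of 22746 probe sets were called in wild type, 3282 higher and 6540 lower, so that 33.4% of the calls were higher. Among the 4405 calls of at least 2-fold, 2076 were higher and 2329 lower. The median log2 change of probe sets above the background limit was -0.27. These values hold for the deposited scaling. With arrays centred on 22 added poly(A) control probe sets, the median of all probe sets moved by -0.30, and 2192 calls were higher and 8968 lower (19.6% higher). Centred on the 12 hybridisation controls it moved the other way, by 0.10, and 3754 calls were higher and 5042 lower (42.7% higher). Changes are reported relative to the deposited scaling throughout.

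By gene group, all 10 named mitochondrial dysfunction markers rose, with a median log2 change of 6.91 (6.90 with values under the background limit set to it), both over all probe sets and adjusted over the list alone. UPOX (AT2G21640) went from 45.2 ± 17.1 to 3679 ± 188, AT12CYS-2 (AT5G09570) from 4.94 ± 0.234 to 119 ± 55.5, and AT2G41730 rose 170.1-fold. The 4 named detoxification genes, of 28 written, all rose, with a median of 7.20 (6.49 at the limit). Besides GSTU25, which is on both lists, these were UGT73B4 (AT2G15490, at least 135-fold), GSTU22 (AT1G78340, at least 28.2-fold) and UGT73B5 (AT2G15480, 66.3-fold), which encode glucosyltransferases and a glutathione transferase. All 3 rapid stress genes rose, with a median of 3.27: the zinc-finger repressor gene STZ (AT1G27730) 30.2-fold, WRKY6 (AT1G62300) 9.62-fold and WRKY53 (AT4G23810) 2.52-fold. By camera the adjusted p was 7.85e-12 for the markers, 0.000166 for detoxification and 0.00158 for rapid stress, against 0.0582, 0.125 and 0.125 with an estimated correlation. The 25S ribosomal RNA probe set was higher on the same arrays by 0.84.

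No other list was called by camera in wild type. Of 5 alternative respiration genes, the alternative NADH dehydrogenase genes NDB4 (AT2G20800, from 2.89 ± 0.104 to 80.1 ± 35.5) and NDB2 (AT4G05020, 10.3-fold) rose, while NDB1 (AT4G28220, 1.49-fold) and NDC1 (AT5G08740, 1.46-fold) fell (camera adjusted p = 0.616). Of 13 genes of complex III and cytochrome c, 6 fell by little, such as the processing peptidase subunit gene MPPBETA (AT3G02090, 1.35-fold), AT5G40810 (1.45-fold) and AT5G25450 (1.47-fold), and the cytochrome c gene CYTC-2 (AT4G10040) rose 3.24-fold. Their median was -0.20 (camera adjusted p = 0.23, fry adjusted p = 0.0179), and centred on the hybridisation controls -0.11, with 2 called lower and 1 higher. Of 7 photosynthesis genes 4 fell, and 5 adjusted over the list alone, with a median of -0.16 (camera adjusted p = 0.159, fry 0.00578), against -0.07 with 2 called lower in that centring. They were PSBY (AT1G67740, 1.66-fold), LHCB4.2 (AT3G08940, 1.46-fold), LHCB4.1 (AT5G01530, 1.29-fold) and RCA (AT2G39730, 1.1-fold). The expansin genes EXPA8 (AT2G40610, 5.94-fold) and EXPA4 (AT2G39700, 1.61-fold) fell among 3 wall-loosening genes (camera adjusted p = 0.627, fry 0.00377). Of 4 auxin response genes, GH3.3 (AT2G23170) rose 3.46-fold and IAA29 (AT4G32280) fell at least 1.57-fold (camera adjusted p = 0.616). That list had a median of 0.16 and a mean of -0.04, and centred on the poly(A) controls a median of -0.14. The small heat shock gene AT5G51440, which is also the 1 named mitochondrial chaperone, rose 10.6-fold, and AT1G53540 changed by 1.53 ± 0.37 with 1 array above the limit, among 4 heat shock genes (camera adjusted p = 0.35, fry 0.0356). Of 4 senescence markers the called ones were WRKY6 and WRKY53, named above (camera adjusted p = 0.159, fry 2.42e-05). No cold and abscisic acid gene was called among 3 (smallest p: COR15B, AT2G42530, -0.68 ± 0.35, camera adjusted p = 0.827), nor any root marker among 3 (PYK10, AT3G09260, 0.32 ± 0.77, camera adjusted p = 0.751). By limma at an unadjusted p under 0.05, 10942 probe sets passed overall.

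The lists too small for a test are given gene by gene for wild type. The mediator list held the C-type cyclin genes AT5G48640 and AT5G48630, which fell 1.84-fold and 1.75-fold. Of the cell cycle list, AUR2 (AT2G25880), an Aurora kinase gene, fell at least 1.79-fold, and AUR1 (AT4G32830) had 28.0 under mock and 27.2 under antimycin A. The circadian clock gene GI (AT1G22770) fell 1.89-fold. Not called were the defensin gene PDF1.2 (AT5G44420, -1.17 ± 0.63) of the jasmonate list, whose other member JMT (AT1G19640) lay under the limit, UF3GT (AT5G54060, 0.31 ± 0.44, under the limit) and DFR (AT5G42800, 55.6 and 59.0) of the anthocyanin list, and the glucosinolate gene BCAT4 (AT3G19710, -0.15 ± 0.29). Calls lost on leaving out single wild-type arrays were those of NDB1 (any of the 6), RCA (5), EXPA4 (4), AT5G48640 (3) and AT5G25450 (4). Their adjusted p rose up to 0.091, 0.168, 0.101, 0.114 and 0.109.

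The same treatment was then compared within each mutant. In both mutants AT2G32020, AT2G04050 and AT4G28460 were again among the largest rises. AT2G32020 reached 1845 ± 199 in rao1-1 (at least 96.9-fold higher than mock) and 1558 ± 137 in rao1-2 (at least 81.9-fold). AT2G04050 rose at least 116-fold and at least 133-fold, and AT4G28085 171-fold and 236-fold. AT4G28460 rose at least 169-fold in rao1-1 and at least 119.98-fold in rao1-2. AT4G37290 rose at least 45.8-fold in rao1-1, and AT5G62865 rose at least 31.8-fold in rao1-2. The largest falls in rao1-1 were AT3G15720 (at least 7.2-fold), the heat shock protein gene Hsp70-2 (AT5G02490, 21.4-fold), AT3G09580 (20.4-fold), AT4G04750 (at least 4.89-fold) and AT4G20460 (at least 4.14-fold). In rao1-2 they were the zinc-finger gene GIS (AT3G58070, at least 3.66-fold), AT3G09580 (20.9-fold), AT5G41900 (18.4-fold), AT4G04750 (at least 4.82-fold) and AT3G26960 (log2 change -4.33 ± 0.57). Adjusted p-values of these genes were at most 0.0233, and that of Hsp70-2 in rao1-1 rose to 0.0507, 0.0559 and 0.0586 without mock replicate 1, 2 or 3.

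In rao1-1, 9225 probe sets were called, 3590 higher and 5635 lower (38.9% higher), and in rao1-2 9756, 3550 higher and 6206 lower (36.4% higher). Centred on the poly(A) controls, the calls were 2182 higher and 7529 lower in rao1-1 and 2185 higher and 9761 lower in rao1-2. Centred on the hybridisation controls, 12515 were called in rao1-1, 2486 higher and 10029 lower, and 14835 in rao1-2, 2632 higher and 12203 lower. At least 2-fold changes numbered 4058 and 4539. The poly(A) centring moved the median of all probe sets by -0.28 and -0.37, and those of the comparisons between genotypes by at most 0.05 up and -0.09 down. Wild type and rao1-1 shared 7343 calls in the same direction with 12 in opposite directions, wild type and rao1-2 7819 with 8, and the mutants 7683 with 2. For the first pair 518 shared rises and 1620 shared falls would be expected by chance. Across probe sets, which are not independent replicates, the responses correlated with r = 0.910, 0.910 and 0.926.

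The same 3 groups rose in the mutants. In rao1-1, 9 of 10 markers rose, with a median of 5.57 (5.43 at the limit), all 4 detoxification genes with 5.89 (5.67), and all 3 rapid stress genes with 2.75. In rao1-2, 9 of 10 markers rose with a median of 4.26, all 4 detoxification genes with 3.61 (3.54) and all 3 rapid stress genes with 2.43. AT5G09570 was the marker not called in either mutant, with 7.04 ± 1.48 and 9.5 ± 7.16 under antimycin A. Camera's adjusted p was 1.89e-07, 0.00242 and 0.0157 in rao1-1, or 0.228, 0.243 and 0.243 with an estimated correlation. In rao1-2 it was 7.29e-07, 0.0166 and 0.0166, or 0.281, 0.483 and 0.439 with an estimated correlation. Of the 13 complex III and cytochrome c genes, 7 fell and 1 rose in rao1-1 (median -0.27, camera adjusted p = 0.0385), and 8 fell, 10 adjusted over the list alone, and 1 rose in rao1-2 (median -0.35, 0.0166). With an estimated correlation these adjusted p-values were 0.581 and 0.491. Centred on the hybridisation controls the medians were -0.50 and -0.59, with 11 and 12 called lower and 0 higher. In rao1-1 that call was lost without antimycin A replicate 1 (0.0808), replicate 3 (0.056) or mock replicate 2 (0.0798). AT1G51980 fell 1.5-fold in rao1-1 and 1.71-fold in rao1-2, and CYTC-2 rose 2.04-fold and 1.86-fold. The 25S ribosomal RNA probe set was higher by 1.24 and 1.05 on the same arrays.

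Of the other lists, GH3.3 rose 5.61-fold and 2.74-fold in rao1-1 and rao1-2, NDB2 6.16-fold and 3.49-fold, and EXPA4 fell 1.57-fold and 2.54-fold. XTH16 (AT3G23730), a xyloglucan-modifying enzyme gene, rose 2.31-fold in rao1-2, COR47 (AT1G20440), a dehydrin gene, 1.83-fold and the auxin-conjugating enzyme gene WES1 (AT4G27260) 1.59-fold. NDB4 changed by 1.92 ± 0.59 in rao1-1, where 1 array lay above the limit. AT5G51440 rose 5.34-fold in rao1-1 and was not called in rao1-2 (1.07 ± 0.81). PSBY fell 1.35-fold and 1.37-fold. SAG29 (AT5G13170), a senescence marker, changed by 2.31 ± 0.85 in rao1-1 with 1 array above the limit. The camera adjusted p of these lists was at least 0.145 in rao1-1 and 0.413 in rao1-2. In rao1-2 the alternative respiration list had a median of 0.07 with a camera direction of down (adjusted p = 0.912), and of -0.30 centred on the poly(A) controls. Of the small lists, PDF1.2 fell 4.71-fold and 5.54-fold, AT5G48630 1.39-fold and 1.38-fold, AT5G48640 2.11-fold in rao1-1, and in rao1-2 AUR2 fell at least 1.96-fold, AUR1 2.15-fold and BCAT4 2.08-fold. GI was not called in rao1-1 (-0.16 ± 0.17) or rao1-2 (0.20 ± 0.17), nor was DFR (0.48 ± 0.73 and 0.09 ± 0.73). Many of these calls rest on single arrays: in rao1-1 those of NDB4, WRKY53, AT5G51440, PDF1.2, EXPA4, AT5G48630, CYTC-2 and SAG29, and in rao1-2 those of NDB2, NDB1, WRKY53, WES1, AT5G48630, AUR2, AUR1, CYTC-2, AT5G25450 and COR47 were lost on leaving out at least 1 of the 6 arrays compared. The highest adjusted p was 0.225 for SAG29, without replicate 1 of rao1-1 antimycin A, and 0.197 for CYTC-2, without replicate 1 of rao1-2 mock.

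The central comparison asked whether the response to antimycin A differed between the mutants and wild type. AT12CYS-2 (AT5G09570) was the named marker with the largest difference: its level under antimycin A was 119 ± 55.5 in wild type, 7.04 ± 1.48 in rao1-1 and 9.5 ± 7.16 in rao1-2, at similar levels under mock (4.94, 5.23 and 5.04). Its difference in response, mean of both mutants minus wild type, was -3.92 ± 0.51 on the log2 scale (adjusted p = 0.00411). AT2G32020 reached 5022 in wild type, 1845 in rao1-1 and 1558 in rao1-2, with a difference of -1.62 ± 0.18 (adjusted p = 0.000779). Other transcripts that rose less in the mutants were AT5G57510 (-3.14, with 267, 29.7 and 41.4 under antimycin A), AT3G17110 (-2.87), AT5G41680 (-2.20), AT4G31875 (-2.26), AT2G41800 (-2.94), AT1G12030 (-2.41) and AT5G60350 (-2.31). AT5G09570, AT3G17110 and the last 3 lay under the background limit on every array of both mutants, so that these are fitted values and not bounds. The tetraspanin gene TET9 (AT4G30430, -3.31) and the chalcone isomerase-like gene CHIL (AT5G05270, -2.14) also had negative differences, but with a raised mock level: TET9 had 4.8, 41.2 and 44.3 under mock in wild type, rao1-1 and rao1-2 and 791, 893 and 658 under antimycin A.

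Positive differences belonged mostly to transcripts that fell in wild type and had lower means in the mutants under mock. AT5G53710 (3.23 ± 0.23, adjusted p = 1.09e-05) went from 52.1 ± 11.4 to 4.72 ± 0.377 in wild type and lay at 5.35 ± 0.504 and 6.99 ± 2.26 under mock in rao1-1 and rao1-2. AT1G56710 (2.38) and AT1G20070 (3.00) also had their highest mock mean in wild type, as had AT5G52850 (1.49), AT1G79770 (1.35), AT4G18840 (1.33), AT1G50280 (1.25), AT5G18430 (1.22) and AT3G06520 (1.18). WSD1 (2.16) differed from these: its level under antimycin A was 5.04 in wild type but 57.5 in rao1-1 and 42.2 in rao1-2, from 126, 184 and 409.9 under mock. With values under the limit set to it, the calls of WSD1, AT5G52850, AT4G18840, AT1G50280, AT5G18430, AT3G06520, TET9, AT2G41800, AT1G12030, AT5G60350 and CHIL were lost. The calls of AT1G20070, AT5G52850, AT1G79770, TET9 and CHIL were lost on leaving out any 1 of at least 9 of the 18 arrays (adjusted p up to 0.113, 0.119, 0.106, 0.113 and 0.0879). That of AT1G50280 was lost without any 1 of 2 (up to 0.0569).

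Over all probe sets, 90 were called for both mutants against wild type, 50 higher and 40 lower, 61 of them at least 2-fold. For rao1-1 alone 84 were called (48 higher, 36 lower) and for rao1-2 alone 45 (19 higher, 26 lower), and 26 were shared in the same direction with 0 opposite by limma (unadjusted, 2458 and 2226 probe sets passed). Independent lists would share 0.0401 rises and 0.0412 falls. The log2 differences of the mutants correlated across probe sets with r = 0.633, against 0.498 in simulations of unchanged groups that share the wild-type arrays, with a covariance of 0.144 against 0.0558, and part of the excess of r may come from those shared arrays. In rao1-1 the largest were AT5G53710 (3.42), WSD1 (2.97), AT1G56710 (2.66), AT5G52850 (1.92) and AT4G18840 (1.63), and AT5G09570 (-4.05), AT5G57510 (-3.53), AT3G17110 (-3.21), AT2G41800 (-2.91) and AT4G31875 (-2.90). In rao1-2 they were AT5G53710 (3.03), AT1G02670 (2.27), AT1G56710, AT1G50280 (1.69) and AT1G72840 (1.43), and AT5G09570 (-3.79), AT2G41800 (-2.98), CHIL (-2.63), AT3G17110 (-2.52) and AT1G12030 (-2.40). AT1G72840 lay under the limit on every array, and AT1G02670 on all but those of rao1-2 under antimycin A. In rao1-1 the calls of AT5G52850 and AT5G57510, and in rao1-2 those of AT1G72840, AT5G09570, CHIL and AT1G12030, were lost on leaving out at least 1 array, with adjusted p up to 0.0753, 0.0521, 0.113, 0.0574, 0.0811 and 0.0745. For AT5G57510 this was replicate 2 of rao1-1 mock, and for AT5G09570 replicate 2 of rao1-2 antimycin A or replicate 3 of wild-type antimycin A.

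These counts depended on single arrays. The 90 calls became 298 without replicate 1 of rao1-2 mock, 171 without replicate 1 of wild-type antimycin A, 177 without replicate 3 of wild-type mock and 56 without replicate 2 of rao1-1 mock. The 84 calls for rao1-1 became 144 without replicate 1 of wild-type antimycin A or replicate 3 of wild-type mock, 55 without replicate 3 of rao1-1 antimycin A or of rao1-1 mock, 52 without replicate 2 of wild-type antimycin A and 40 without replicate 2 of rao1-1 mock. The 45 calls for rao1-2 became 324 without replicate 1 of rao1-2 mock, 103 without replicate 1 of wild-type antimycin A, 101 without replicate 3 of wild-type mock and 27 without replicate 2 of rao1-2 antimycin A. The 26 shared calls became 63, 61 and 69 without replicate 1 of rao1-2 mock, replicate 1 of wild-type antimycin A or replicate 3 of wild-type mock. With array weights, 263 were called for both mutants, 195 for rao1-1, 219 for rao1-2 and 58 shared, and without the dimmest probe sets 56, 46, 21 and 10. With values at the limit 142, 72 and 46 were called for rao1-1, rao1-2 and shared, and a fit to only the arrays compared called 26 for rao1-2. Centred on the 12 hybridisation controls, which moved the median difference of all probe sets by -0.34 for both mutants, 7253 were called for both mutants (7152 lower), 149 for rao1-1 (15 higher, 134 lower) and 6110 for rao1-2 (73 higher, 6037 lower), with 76, 51 and 43 of the calls reported.

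**Figure D1:**
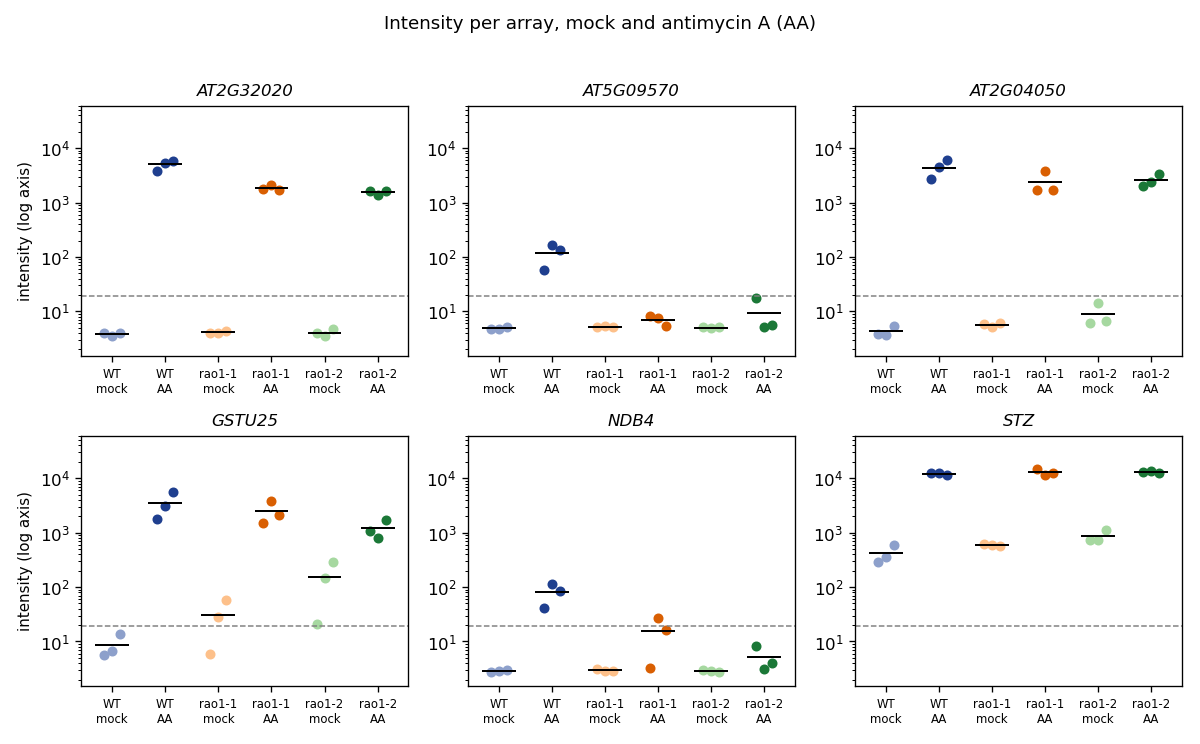
Intensity (log axis) of 6 transcripts of the fixed lists in the 6 groups, with 1 point per array, a black bar at the mean of 3 arrays and the background limit as a dashed line. AT5G09570 had a mean of 119 in wild type under antimycin A and lay under the limit in both mutants, while STZ was similar in the 3 genotypes under antimycin A.

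By gene group, the list of mitochondrial dysfunction markers passed camera for the difference in response. All 10 had negative differences for both mutants against wild type, with a median of -1.57 (-1.51 at the limit), of which 2 were called over all probe sets and 4 adjusted over the list alone. For rao1-1 the median was -1.43 (-1.05), with 9 of 10 negative and 2 called either way, and for rao1-2 -1.71 (-1.61), with 10 of 10 negative, 2 called and 6 adjusted over the list alone. Camera gave adjusted p-values of 2.49e-11, 2.09e-07 and 1.62e-12, and with an estimated correlation the adjusted p was 0.067, 0.232 and 0.0482. The last was the 1 list call that held with an estimated correlation among 36 over all comparisons. Of 12 lists, camera called 1, 4 and 4 for rao1-1, rao1-2 and both, and fry 0, 2 and 1. Under mock the markers' median was 0.32 in rao1-1 and 0.91 in rao1-2 against wild type, but 0.00 and 0.26 at the limit, and a raised mock level enters a difference in response with a negative sign.

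The 4 detoxification genes had a median difference of -2.55 (-2.12 at the limit) for both mutants, with 0 called by limma over all probe sets and 3 adjusted over the list alone. For rao1-2 it was -3.61 (-2.92), with 0 called and 3 adjusted over the list alone, and UGT73B4 had the smallest p (-4.24 ± 0.91, adjusted p = 0.115). Camera gave 9.43e-05 and 1.15e-06 (adjusted p = 0.14 and 0.0518 with an estimated correlation), and for rao1-1 0.0503, which was not called. The 3 rapid stress genes had -0.68 for both mutants (camera adjusted p = 0.0247) and -0.84 for rao1-2 (0.0174), with 0 called over all probe sets and 1, STZ, adjusted over the list alone (-0.73 ± 0.26). With an estimated correlation the adjusted p was 0.337 and 0.284. The 13 complex III and cytochrome c genes had -0.10 for both mutants, 10 of 13 negative, and -0.11 for rao1-2 (camera adjusted p = 0.0365 and 0.0174), with 0 called either way. With an estimated correlation the adjusted p was 0.448 and 0.406. Centred on the hybridisation controls the complex III medians were -0.44 and -0.45, with 4 called lower in each, the rapid stress medians -1.01 and -1.18 with 1 called lower, and the detoxification medians -2.89 and -3.95 with 3 called lower. The markers then had -1.90 and -2.05, with 6 called lower in each. The rapid stress calls were lost without wild-type mock replicate 1 (0.129 for both mutants, 0.0669 for rao1-2) or 2 (0.0827 and 0.0594). For rao1-2 this also held without rao1-2 antimycin A replicate 1 (0.0508) or mock replicate 2 (0.0521). The complex III call for both mutants was lost without any 1 of 9 arrays (adjusted p up to 0.157). That for rao1-2 was lost without any 1 of 6 (up to 0.131).

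**Figure D2:**
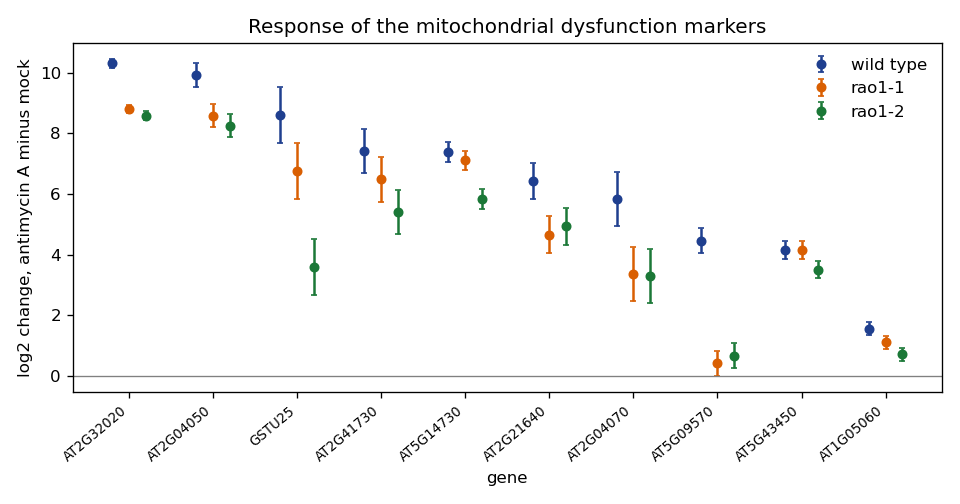
Log2 change from mock to antimycin A of the 10 named mitochondrial dysfunction markers in wild type, rao1-1 and rao1-2, with bars for the SE of the fit to all arrays. AT2G32020 changed by 10.32, 8.80 and 8.59 in the 3 genotypes, fitted values from mock levels under the limit.

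None of the other lists was called by camera for these differences, and adjusted over the list alone 2 alternative respiration genes, 1 heat shock and 1 auxin gene passed for both mutants. NDB4 had 80.1 ± 35.5 in wild type, 15.4 ± 11.7 in rao1-1 and 5.09 ± 2.73 in rao1-2 under antimycin A, with a difference of -3.37 ± 0.73 that missed the threshold (adjusted p = 0.0724). GI had a difference of 0.94 ± 0.21 (adjusted p = 0.0942), IAA29 1.74 ± 0.59, EXPA8 1.93 ± 0.80 and PSBW (AT2G30570) 0.20 ± 0.08, none of them called, nor were AT1G53540 (-1.51), PDF1.2 (-1.18), AT5G48630 (0.34), AUR2 (0.56), AT5G51440 (-1.67), UF3GT (-0.31), BCAT4 (-0.53), COR15B (0.32), EXPA18 (AT1G62980, 0.23), WRKY53 (-0.49) and CYTC-1 (AT1G22840, -0.37). The smallest camera adjusted p among the other lists was 0.0503, for photosynthesis in rao1-1, and it was 0.0572 for both mutants. The cold and abscisic acid list had a median of 0.20 and a camera direction of down, and the senescence list a median of -0.08 and a mean of 0.13.

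Transcripts that responded in the mean of the 3 genotypes were also compared as a whole, and their differences depended on the scaling. Among 2135 probe sets that rose at least 2-fold, the median difference between rao1-1 and wild type was -0.20 (quartiles -0.71 and 0.23, 61.0% negative), and 25 were called. The mean difference, which was the value tested, was -0.29 (two-sided exact permutation p = 0.04 over 400 relabellings). For rao1-2 the median was -0.11 (56.4% negative), with 20 called, and the mean -0.22 (exact permutation p = 0.21). Among 2246 that fell, the median was 0.07 in rao1-1 (15 called) and -0.05 in rao1-2 (12 called). The means were 0.08 (exact permutation p = 0.625) and -0.0056 (exact permutation p = 0.975). Adjusted over these 4 tests, the p-values were 0.16 and 0.42 for the risen and 0.833 and 0.975 for the fallen, none past the threshold. With responders chosen by adjusted p alone, the median for risen probe sets was 0.05 in both mutants. The medians of the same responders centred on the hybridisation controls were -0.53 and -0.45 for the risen and -0.26 and -0.39 for the fallen in rao1-1 and rao1-2.

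Seedlings sprayed with water were compared next, to ask how the mutants differed from wild type without the inhibitor. In rao1-1, AT5G62210 had the largest fitted rise, at 133 ± 24.0 against 4.83 ± 1.54 in wild type. It was at least 6.91-fold higher (adjusted p = 0.000114). AT4G23680 was 14.8-fold higher, AT1G43910 8.57-fold, TET9 at least 1.81-fold, the inositol phosphatase gene SAL2 (AT5G64000) at least 4.35-fold and AT3G28220 6.98-fold. AT3G44970 was 6.78-fold higher, AT1G70270 6.37-fold, AT4G19430 6.03-fold and AT1G67760 at least 2.98-fold. AT2G33850 was 16.3-fold lower, with 59.2 ± 35.2 against 883 ± 179 in wild type and 934 ± 141 in rao1-2. AT3G53980 was at least 5.93-fold lower, AT5G52070 at least 6.15-fold, AT5G53710 at least 2.7-fold, AT1G51090 9.37-fold, AT4G28140 7.96-fold, AT1G20070 6.91-fold, AT1G56710 at least 1.83-fold and AT3G17640 5.23-fold. AT5G12940 (-2.33 ± 0.36) lay under the limit in both groups. In all 918 probe sets were called, 419 higher and 499 lower, 362 of them at least 2-fold. The calls of AT1G43910, SAL2, AT3G28220, AT3G53980, AT1G51090 and AT3G17640 were lost on leaving out at least 1 array, with adjusted p up to 0.107. The count itself was 534, 383 and 562 without rao1-1 mock replicate 1, 2 or 3, and 492 and 505 without wild-type mock replicate 1 or 2. With array weights it was 2472, and centred on the hybridisation controls 5881 (5515 higher), 726 of them among the 918.

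In rao1-2, AT5G62210 (at least 4.53-fold), AT4G23680 (16.5-fold) and TET9 (at least 2.3-fold) had the largest fitted rises under mock. CHIL was at least 3.26-fold higher, AT3G10930 5.42-fold, AT4G23870 4.28-fold, AT4G10270 4.25-fold, AT1G64700 at least 1.53-fold, AT3G47540 4.1-fold and the carboxypeptidase-like gene scpl31 (AT1G11080) 4.04-fold. AT1G51090 was 13.1-fold lower, AT4G28140 7.98-fold, AT5G53710 at least 2.7-fold, AT1G20070 5.75-fold, SIS (AT5G02020) 5.42-fold, AT3G15720 4.95-fold, AT1G56710 at least 1.83-fold, AT5G52070 4.5-fold, AT1G79770 at least 2.47-fold and the cold-regulated gene COR27 (AT5G42900) 3.78-fold. In all 312 probe sets were called, 144 higher and 168 lower, 168 of them at least 2-fold. The count was 1442 without rao1-2 mock replicate 1, 181 and 182 without replicate 2 or 3, and 188 and 509 without wild-type mock replicate 2 or 3. It was 829 with array weights and 14 in a fit to only the arrays compared, and centred on the hybridisation controls 462 were called, 371 higher, 234 of them among the 312. The calls of AT4G10270, AT1G64700, scpl31, AT1G51090, AT1G20070, SIS and AT3G15720 were lost on leaving out at least 1 of rao1-2 mock replicates 2 and 3 and the 3 wild-type mock arrays, with adjusted p up to 0.184.

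The mutants shared 235 of these calls in the same direction, 102 higher and 133 lower, with 0 opposite by limma. Independent lists would share 2.65 rises and 3.69 falls. Sharing wild-type arrays favours such agreement. Log2 differences from wild type correlated across probe sets with r = 0.755, against 0.501 in simulations with shared wild-type arrays (covariance 0.120 against 0.0282). AT5G62210, AT4G23680, TET9, AT5G53710, AT1G56710, AT1G20070, AT1G51090, AT4G28140 and AT5G52070 were among the 10 largest fitted changes of their direction in both. The overlap was 560 without rao1-2 mock replicate 1, 138 and 149 without replicate 2 or 3, and 148 and 394 without wild-type mock replicate 2 or 3. With array weights 610 calls were shared, and with values at the limit 353.

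**Figure D3:**
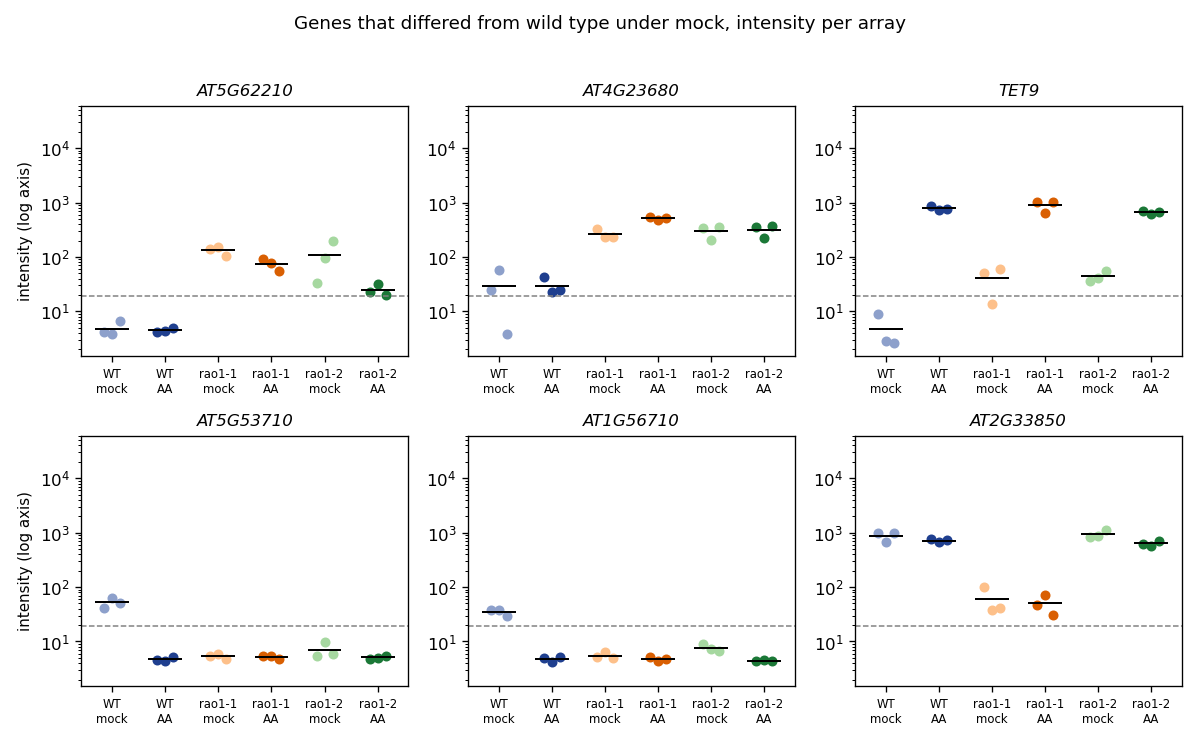
Intensity (log axis) of 6 transcripts with large differences from wild type under mock, in the 6 groups, with 1 point per array, a black bar at the mean of 3 arrays and the background limit as a dashed line. AT5G62210 had means of 4.83, 133 and 109 under mock in wild type, rao1-1 and rao1-2, and AT2G33850 883, 59.2 and 934.

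By gene group under mock, the list of 13 complex III and cytochrome c genes passed camera in both mutants, with medians of 0.24 in rao1-1 and 0.23 in rao1-2. In each mutant 5 of 13 were higher adjusted over the list alone, and over all probe sets CYTC-2 was called in rao1-1 (2.39-fold, adjusted p = 0.0487) and 0 by limma in rao1-2. Camera's adjusted p was 0.000447 and 2.61e-06, against 0.78 and 0.176 with an estimated correlation. The 7 photosynthesis genes had medians of -0.11 and -0.10, with 0 called over all probe sets or adjusted over the list alone (camera adjusted p = 0.0285 and 0.0137). With an estimated correlation their adjusted p was 0.78 and 0.426. Centred on the hybridisation controls these medians were 0.08 and 0.07, and those of complex III and cytochrome c 0.43 and 0.40, with 7 and 0 called higher. In rao1-2 the markers had a median of 0.91 (0.26 at the limit), with AT5G14730 called (2.75-fold) and 2 adjusted over the list alone (camera adjusted p = 0.00048, or adjusted p = 0.207 with an estimated correlation). The 4 detoxification genes had 2.08 (1.68 at the limit), with 0 called and 2 adjusted over the list alone (0.000742, or adjusted p = 0.176 with an estimated correlation). Of the rapid stress genes STZ was 2.14-fold higher, and the list had 0.75 (0.0137, or adjusted p = 0.207 with an estimated correlation). The cold and abscisic acid list passed camera too, with a median of -1.40, 0 called and all 3 adjusted over the list alone, such as COR15B (-1.40 ± 0.35), at 0.00179, or adjusted p = 0.176 with an estimated correlation. In rao1-1 the markers (0.32), detoxification (0.09), rapid stress (0.30) and cold (-0.63) lists were not called, with 0, 0, 1 and 1 genes adjusted over the list alone. Of the 12 lists, fry called 0 in rao1-1 and 2 in rao1-2, against 2 and 6 by camera.

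Further genes under mock were WES1, 1.96-fold higher in rao1-1 (adjusted p = 0.0378) and at 1.02 ± 0.24 in rao1-2 (adjusted p = 0.0544), and EXPA8, not called in rao1-1 (-2.40 ± 0.66). The expansin list in rao1-1 had a median of 0.48 and a mean of -0.47. Of the small lists none was called: AT5G48630 had -0.27 and -0.31, GI -0.54 and -0.60, DFR -1.40 and -2.26, AT5G51440 -0.68 and 0.47, BCAT4 0.31 and 0.36, and JMT 0.11 and 0.43. Several of the calls under mock rest on single arrays. Those of CYTC-2 and WES1 in rao1-1 were lost without any 1 of 5 and of 6 arrays compared, with adjusted p up to 0.191 (without rao1-1 mock replicate 2) and 0.129 (without wild-type mock replicate 2). In rao1-2, STZ was lost without any 1 of 3 arrays (up to 0.0826), and AT5G14730 without any 1 of 4 (up to 0.123). The photosynthesis call was lost without any 1 of 4 arrays in rao1-1 (up to 0.207) and of 3 in rao1-2 (up to 0.173). The rapid stress call in rao1-2 was lost without rao1-2 mock replicate 2 (0.0693) or wild-type mock replicate 1 or 2 (0.0718 and 0.0516).

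The levels reached under antimycin A were also compared. AT4G23680 was 17.9-fold higher in rao1-1 and 10.9-fold in rao1-2 than in wild type, AT5G62210 at least 3.87-fold and at least 1.29-fold, and WSD1 at least 3.0-fold and at least 2.14-fold. In rao1-1 the sugar transporter gene SWEET13 (AT5G50800) was at least 3.35-fold higher and AT3G44970 9.15-fold, and in rao1-2 AT1G69570 5.66-fold and AT1G02670 at least 1.8-fold. AT5G09570 was at least 5.7-fold lower in rao1-1 and at least 5.7-fold in rao1-2, and the expansin gene EXPA20 (AT4G38210) at least 2.2-fold and at least 2.2-fold. In rao1-1 AT1G68620 was at least 9.68-fold lower, AT2G33850 15.2-fold and AT5G57510 10.8-fold. In rao1-2 NDB4 was at least 3.9-fold lower, AT1G02470 at least 4.5-fold and AT3G17110 at least 5.97-fold. In all 743 probe sets were called for rao1-1 (403 higher, 340 lower) and 560 for rao1-2 (305 higher, 255 lower). Most calls were lower when centred on the hybridisation controls, with 157 higher and 464 lower for rao1-1 and 112 higher and 531 lower for rao1-2. They shared 284 in the same direction, with 0 opposite by limma, against 5.40 rises and 3.81 falls for independent lists. They correlated with r = 0.699 across probe sets against 0.501 in the simulations (covariance 0.111 against 0.0280). Without rao1-1 antimycin A replicate 1 the first count was 447, and without wild-type antimycin A replicate 2 or 3 it was 458 and 487. The second was 295, 266 and 306 without rao1-2 antimycin A replicate 1, 2 or 3, and 313 and 265 without wild-type antimycin A replicate 2 or 3. The overlap was 153, 165 and 148 without rao1-2 antimycin A replicate 1, 2 or 3, and 163 and 171 without wild-type antimycin A replicate 2 or 3. Array weights gave 1738 calls for rao1-2 and 496 shared, and a fit to only the arrays compared 58 and 109 for rao1-1 and rao1-2. On such omissions the calls of SWEET13 (without wild-type antimycin A replicate 2 or 3) in rao1-1 and of AT4G23680, AT5G62210 and AT1G02470 in rao1-2 were lost, with adjusted p up to 0.0894, 0.0691, 0.0663 and 0.0687.

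By gene group under antimycin A, the marker list passed camera in both mutants, with medians of -0.63 in rao1-1 (9 of 10 negative) and -0.73 in rao1-2 (10 of 10). In each, AT5G09570 and AT2G32020 were called, and 3 adjusted over the list alone. Camera's adjusted p was 1.44e-05 and 8.75e-06, against 0.261 and 0.22 with an estimated correlation. Of the detoxification genes, GSTU22 was 4.81-fold lower in rao1-2, where the list had -1.47 (camera adjusted p = 0.00966, or adjusted p = 0.228 with an estimated correlation), and in rao1-1 none was called (-1.01, camera adjusted p = 0.0617). The cold and abscisic acid genes had medians of -1.06 and -1.34, with 0 called by limma and 1 and 2 adjusted over the list alone (camera adjusted p = 0.029 and 0.0471). With an estimated correlation their adjusted p was 0.261 and 0.228. Of alternative respiration, NDB4 was lower in both (6.56-fold in rao1-1), with a list median of -0.15 in rao1-2 (camera adjusted p = 0.0871, fry 0.00979). WES1 was 2.29-fold and 2.64-fold higher, and AT1G53540 differed by -1.51 and -1.52 with 1 wild-type array above the limit. The rapid stress genes differed by medians of -0.22 and -0.09 and were not called. The cold call was lost in rao1-1 without rao1-1 antimycin A replicate 3 (0.0765) or wild-type antimycin A replicate 1 (0.0977), and in rao1-2 without rao1-2 antimycin A replicate 2 (0.133) or wild-type antimycin A replicate 1 (0.228), and with the replicate number as a block (0.0712). NDB4 in rao1-1 was lost without wild-type antimycin A replicate 2 or 3 (0.0926 and 0.0781), and WES1 without rao1-1 antimycin A replicate 1 (0.0582). GSTU22 in rao1-2 was lost without any 1 of 4 arrays (up to 0.108), and AT1G53540 without any array of either mutant (up to 0.104 and 0.124).

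Last, the mutants were compared with each other. AT2G33850 was higher in rao1-2 than in rao1-1, by 4.12 ± 0.34 on the log2 scale under mock and 3.75 ± 0.34 (13.5-fold) under antimycin A. Under mock AT5G12940 (at least 1.03-fold), AT3G61840 (at least 1.25-fold) and AT2G37980 (at least 1.29-fold) were also higher, and AT4G17470 (at least 5.05-fold), AT4G24480 (at least 2.37-fold), the transcription factor gene bZIP58 (AT1G13600, at least 1.59-fold) and ZW9 (AT1G58270, 2.79-fold) lower. AT2G20515 (2.03) and AT1G72140 (-1.32) were called at levels around or under the limit. Under antimycin A, AT5G42680 (5.16-fold), AT4G33420 (4.67-fold), AT1G02670 (at least 1.8-fold) and AT2G30740 (2.52-fold) were higher in rao1-2, and AT2G28410 (3.51-fold), AT5G44060 (2.52-fold), AT5G35400 (2.42-fold), AT1G73700 (at least 1.02-fold) and iqd21 (AT3G49260, 2.17-fold) lower. The counts were 33 under mock (15 higher, 18 lower), 23 under antimycin A (13 higher, 10 lower) and 0 by limma for the difference in response, where 1504 passed at an unadjusted p under 0.05. Without rao1-2 mock replicate 1 they were 185 under mock and 57 for the difference in response. Under antimycin A they were 113 and 58 without rao1-1 replicate 1 or 2, and 14 and 43 without rao1-2 replicate 2 or 3. For the difference in response, leaving out rao1-1 antimycin A replicate 1, 2 or 3 gave 11, 5 and 2, rao1-2 antimycin A replicate 3 or 1 gave 6 and 2, rao1-2 mock replicate 2 gave 3 and rao1-1 mock replicate 1 gave 1. Array weights gave 170, 604 and 87 calls under mock, under antimycin A and for the difference in response, values at the limit 40 and 6 for the last 2, and a fit to only the arrays compared 2 and 3 for the first 2.

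By gene group, the list of 4 detoxification genes passed camera for rao1-2 against rao1-1 under mock, with a median of 2.07 (0 called by limma, 1 adjusted over the list alone, camera adjusted p = 0.000185, or adjusted p = 0.278 with an estimated correlation). Their difference in response had a median of -2.32 (0 called, 3 adjusted over the list alone, 0.00256, or adjusted p = 0.439 with an estimated correlation). The markers had 0.48 under mock (0 called, 1 adjusted over the list alone, 0.00467, or adjusted p = 0.49 with an estimated correlation). Under antimycin A no list was called by camera, and fry called alternative respiration (median -0.23, fry adjusted p = 0.00911). Fry called 0 lists under mock and 0 in response. UGT73B4 had 14.2 ± 3.82 in rao1-1 and 120.4 ± 105 in rao1-2 under mock. The marker call was lost without rao1-2 mock replicate 2 (0.0786) or 3 (0.125), and the detoxification call for the difference in response without rao1-1 antimycin A replicate 2 (0.0601). The calls of AT2G37980, AT4G24480, bZIP58 and ZW9 under mock were lost without any 1 of at least 4 arrays compared (adjusted p up to 0.108, 0.115, 0.196 and 0.18), and those of AT5G42680, AT4G33420, AT2G28410, AT5G44060, AT5G35400, AT1G73700 and iqd21 under antimycin A without any 1 of at least 3 (up to 0.142).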

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

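All tests of explanations in this part were chosen after the results were seen, while the splits of the arrays were planned. What drew attention was a difference between groups, tested as the difference between genotypes in the response to antimycin A, for the counts, genes and lists of the next paragraph, and a signal in control probe sets for the 25S ribosomal RNA and the hybridisation controls.

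The difference in response was called for 84 probe sets in rao1-1, 45 in rao1-2 and 90 for the mean of both mutants against wild type. Among the genes, log2 differences for both mutants were 3.23 for AT5G53710, 3.00 for AT1G20070, 2.38 for AT1G56710, 2.16 for WSD1, 1.49 for AT5G52850, 1.35 for AT1G79770, 1.33 for AT4G18840, 1.25 for AT1G50280, 1.22 for AT5G18430 and 1.18 for AT3G06520. On the negative side they were -3.92 for AT5G09570, -3.31 for TET9, -3.14 for AT5G57510, -2.94 for AT2G41800, -2.87 for AT3G17110, -2.41 for AT1G12030, -2.31 for AT5G60350, -2.26 for AT4G31875, -2.20 for AT5G41680, -2.14 for CHIL and -1.62 for AT2G32020. The lists had medians of -1.57 for the mitochondrial dysfunction markers, -2.55 for detoxification, -0.68 for rapid stress and -0.10 for complex III and cytochrome c. The 25S ribosomal RNA probe set rose with antimycin A by 0.84 in wild type, 1.24 in rao1-1 and 1.05 in rao1-2 (log2). Under mock the hybridisation control BioC-3 differed from wild type by -0.61 in rao1-1 and -0.37 in rao1-2, and its difference in response was 0.46 for both mutants. Centred on the 12 hybridisation controls, 7253 probe sets were called for the difference in response of both mutants, and the markers had a median of -1.90. The BioC, BioD and Cre controls did not shift alike, so 1 shift per array does not describe them, and a difference in handling of the mutants' mock arrays cannot be told apart from genotype under mock.

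The first pattern weighed is the negative difference in response of the 10 mitochondrial dysfunction markers in the mutants, with a median of -1.57. A weaker response of all responders stays open. A median as low came in 0.32% of 10000 random sets of risen probe sets matched on mean response. Their median was -0.55 (95% range -1.24 to 0.04), but the sets ignore the estimated correlation, with which camera did not pass. The tables argue against floor values: at the limit the median was -1.51 (spread between arrays 0.72). Raised mock levels in the mutants as the whole cause stay open. Under antimycin A the markers' median was -0.76 from wild type, with 10 of 10 lower. That lies within the spread over all arrays (0.82) but beyond that of the treated arrays (0.46). Under mock the median was 0.67, with 8 of 10 higher, in part from values under the limit. At the limit it was 0.00 in rao1-1 and 0.26 in rao1-2. The wider spread was replaced by the narrower after the outcome was seen, then restored. With the narrower the test is undecided. AT5G09570 and AT2G32020 were both called lower under antimycin A in both mutants, the smallest of the 4 falls being -1.43. These genes were chosen after their values were seen, which fixed the outcome of their test, so it excludes no explanation. An effect of the genotype on these markers is a hypothesis.

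The second pattern is the larger number of probe sets that fell than rose after antimycin A, with 33.4%, 38.9% and 36.4% of calls higher in wild type, rao1-1 and rao1-2. Whether the scaling of the deposited values made it could not be decided, since with arrays centred on the 14204 probe sets above the background limit the shares were 36.2%, 40.7% and 38.8%, on both sides of the 40% that the test named. A scaling that hides a larger fall could not be decided either: centred on the 22 added poly(A) control probe sets the shares were 19.6%, 22.5% and 18.3%, but on the 12 hybridisation controls 42.7%, 19.9% and 17.7%, so that the added controls disagree in wild type. The labels do not state at which stage these controls were added, so a lower amount of messenger RNA and a difference in handling cannot be told apart. The treatment itself stays among the open explanations, and no test separated it from the scaling.

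The third pattern is that transcripts encoded in the mitochondrial genome, 23 probe sets for 16 genes, were higher after antimycin A, with medians of 0.60, 1.05 and 1.05 in wild type, rao1-1 and rao1-2 and 11, 15 and 14 called higher and 0 lower by limma (camera p = 0.017, 0.00685 and 0.00867 with an estimated correlation). The scaling of the deposited values as the cause could not be decided: the wild-type median was 0.64 with arrays centred on probe sets above the limit, which moved it little, and 0.70 on the hybridisation controls, but 0.30 on the poly(A) controls, on the other side of the 0.5 that the test named. A larger share of RNA without poly(A) tails could not be decided: over all 69 plastid probe sets the medians were -0.0121, 0.12 and 0.18, of which the last 2 would turn negative with the poly(A) centring, while the 8 plastid probe sets as dim as the mitochondrial ones had 0.09, 0.85 and 0.73. The first form of that test, over all plastid probe sets, would have excluded it, but their median intensity of 5651 lies above the highest mitochondrial one of 504, and the rise of the 25S ribosomal RNA, which has no such tail, goes with this explanation. Copies of mitochondrial DNA in the nuclear genome were not tested, and the treatment stays among the open explanations.

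Other splits of the same arrays were counted for each number of calls. For the difference in response of rao1-1, 4 of 100 splits gave at least 84 calls (highest other 547, from a split that exchanged all mock arrays and 1 treated array of each genotype). For both mutants, 3 of 100 gave at least 90 (highest other 223). These shares lie under the planned 1 in 20, but they come from a random sample of splits and were not adjusted over the tests, so chance is not excluded. Nor is it excluded for rao1-2, where 8 of 100 gave at least 45 (highest other 1059, from a split that exchanged all treated arrays). These high counts point to a structure of the samples, since an exchange within 1 treatment turns the genotype differences under mock and antimycin A into a difference in response. For rao1-2 against rao1-1, with 0 calls by limma and 1504 at an unadjusted p under 0.05, 100 of 100 splits did as well, which a count of 0 brings by construction, so this says nothing about chance (highest other 44).

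The comparisons of 3 arrays with 3 have 10 splits, too few for a share under 0.05. The real counts, with the highest of the other splits, were 9822 and 1 for the response in wild type, 9225 and 0 in rao1-1 and 9756 and 1 in rao1-2. Under mock they were 918 and 11 for rao1-1, 312 and 1001 for rao1-2, and 33 and 10 between the mutants, and under antimycin A 743 and 6, 560 and 5, and 23 and 11. As many calls came from 2 of the 10 splits for rao1-2 under mock and from 1, the real one, for each of the others. The split with 1001 calls exchanged replicate 1 of rao1-2 mock and replicate 3 of wild-type mock. It set replicates 1 against replicates 3, a structure by replicate number.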

How the results depend on the processing

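The alternatives were planned, except for centring on probe sets above the limit and setting values under the limit to it, which were chosen after seeing the data, as were centring on added controls and all alternatives for the overlaps of levels under antimycin A and of differences in response. Numbers of calls that moved by over 1.5 times follow by setting, and the cause was not tested unless given. At an added 2-fold threshold, which lowers counts by its construction, 4405, 4058 and 4539 probe sets were called for the response in wild type, rao1-1 and rao1-2, 362 and 168 for rao1-1 and rao1-2 under mock, 300 and 216 under antimycin A, and 15 between the mutants under antimycin A. With the dimmest probe sets left out, 46, 21 and 56 were called for the difference in response in rao1-1, rao1-2 and both, and 10 were shared by the mutants in response. Array weights gave 195, 219 and 263 for these, 2472 and 829 for rao1-1 and rao1-2 under mock, 1738 for rao1-2 under antimycin A, 170, 604 and 87 between the mutants under mock, under antimycin A and in response, and 610, 496 and 58 shared by the mutants under mock, under antimycin A and in response. Values set to the limit gave 142 and 72 for the difference in response of rao1-1 and rao1-2, 40 and 6 between the mutants under antimycin A and in response, and 353 and 46 shared under mock and in response. Centred on the hybridisation controls, 149, 6110 and 7253 were called for the difference in response in rao1-1, rao1-2 and both, 5881 for rao1-1 under mock and 14835 for the response in rao1-2. With only the arrays compared, a fit with fewer arrays to estimate the spread, 26 were called for the difference in rao1-2, 14 for rao1-2 under mock, 58 and 109 for rao1-1 and rao1-2 under antimycin A, and 2 and 3 between the mutants under mock and antimycin A.

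The median difference among shared responders that rose turned to 0.0463 in rao1-1 and 0.0469 in rao1-2 with responders chosen by adjusted p alone. Chosen by the wild-type response, which favours a smaller response in the mutants by its construction, it was -0.33 and -0.28, and for those that fell 0.30 and 0.19. Of 36 list calls by camera, 1 held with an estimated correlation. The list calls lost were 1 with the replicate block (cold and abscisic acid in rao1-2 under antimycin A, adjusted p = 0.0712), 5 with quantile normalization, 10 without the dimmest probe sets, 11 with values at the limit, 2 each with array weights and centring, and 12 on leaving out at least 1 array. Of the 254 called values of named genes, 10 were lost with the replicate block, 13 with quantile normalization, 37 with values at the limit, 85 with only the arrays compared and 73 on leaving out at least 1 array, and 0 reversed in these settings.

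Leaving out 1 array at a time, which leaves fewer arrays to estimate the spread, gave 8727 to 9289 calls for the response in wild type, 7885 to 10027 in rao1-1 and 8806 to 9254 in rao1-2. For the difference in response it gave 40 to 144 in rao1-1, 27 to 324 in rao1-2, 56 to 298 for both and 0 to 57 between the mutants. Under mock it gave 383 to 964 for rao1-1, 181 to 1442 for rao1-2 and 23 to 185 between the mutants, and under antimycin A 447 to 823, 265 to 579 and 14 to 113. Shared calls were 6590 to 7597 for the responses of wild type and rao1-1, 7159 to 7892 for wild type and rao1-2 and 6802 to 7721 for the mutants, and between the mutants 138 to 560 under mock, 148 to 336 under antimycin A and 18 to 69 in response. The median difference of shared responders was -0.26 to -0.10 (risen) and -0.09 to 0.17 (fallen) in rao1-1, and -0.20 to -0.04 and -0.11 to 0.02 in rao1-2. List calls were 28 to 48.

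With the replicate number as a block, no count moved by over 1.5 times. Of 45 pairs of arrays with the same number in different groups, 25 had a correlation of deviations from the group means over 0.1 (range -0.29 to 0.39, across probe sets), and 13 of 18 arrays correlated best with their own number. The labels do not say that the numbers pair the samples, and the block was not used for the values reported. What the signal over background limits is the dim transcripts: 62.0% of values lay above the limit, and differences of transcripts under it in the mutants are fitted values.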

Other observations

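All tests in this part were chosen after the results were seen, and gene families were formed from the names of the genes, 26 families in each of 6 comparisons. PUB genes encode U-box ubiquitin ligases, which attach ubiquitin to other proteins, and 5 of the 9 named here rose in wild type after antimycin A by limma and 0 fell, with a median log2 change of 0.94 (camera adjusted p = 0.0452 over the 26 families, adjusted p = 0.618 with an estimated correlation). Mean intensity went from 242 to 2608 for PUB23, from 357 to 1417 for PUB22 and from 149 to 535 for PUB24, log2 changes of 3.43, 2.03 and 2.00. PUB26 and PUB43 rose by 1.28 and 0.73, to 181 and 301. In rao1-2, 6 of the 9 were called higher, with a median of 1.25 (adjusted p = 0.0298, and adjusted p = 0.598 with an estimated correlation), and in rao1-1 6 of 9 with a median of 1.22, where the family did not pass (adjusted p = 0.145). No member was called for the difference in response of both mutants. Of the genes that rose, PUB22, PUB23 and PUB24 are known from earlier work as negative regulators of immune responses.

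UBP genes encode proteases that remove ubiquitin, and 8 of the 12 named here were called lower in rao1-2 after antimycin A and 0 higher, with a median of -0.43 (adjusted p = 0.0298, and adjusted p = 0.499 with an estimated correlation). The medians were -0.24 in wild type and -0.29 in rao1-1, with 6 of 12 called lower in each, and the family passed in neither (adjusted p = 0.249 and 0.148). UGT genes encode glycosyltransferases that attach sugars to small molecules. Over 47 of them the difference in response of both mutants had a median of -0.15 (adjusted p = 5.28e-04, and adjusted p = 0.234 with an estimated correlation), with 0 members called by limma, and the largest difference was -4.27 for UGT76B1.

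A hypothesis was that changes shared by both mutants under mock come from a segment or a second mutation linked to the mutated gene, which would be seen as changed genes near it. Among the 200 named genes nearest to CDKE1 by start position on its chromosome, 3 were changed in both mutants, against 109 of 13011 others, a ratio of 1.79 (Fisher's exact p = 0.241), so the test leaves this open. A hypothesis for the detoxification list, with a median difference of 2.07 (log2) between rao1-2 and rao1-1 under mock, was that 1 array of rao1-2 mock carried it. Without replicate 1, 2 or 3 of that group the median was 3.268, 1.743 and 1.195, so no single array made the whole difference, but its size depends on them, and the test was undecided.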
